A study of Mus musculus with 15 samples.

How the data were processed

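The series holds 15 mouse samples, 1 per group: Myc and RNA polymerase II (RNAPII) ChIP-seq at 6 times of a time course in 3T9-MycER fibroblasts, Miz1 ChIP-seq in the same cells without activation and in splenic B cells, and an input library. Peak lists of 14 samples were used; the input enters here only as the control of the submitters' peak calls, and its own signal was not analysed here. There are 20 lists, since each of the 6 RNAPII libraries has both a narrow and a broad list. Groups and times were taken from the labels.

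Reads had been aligned to mm9 with BWA 0.6.2-r126, per the submitters' processing notes, which also name MACS2 2.0.9. Each list is a call on 1 library against a control, with no pooling, per the file headers. Myc and narrow RNAPII peaks came from MACS 1.4.2 with a p cutoff of 1e-08, 1 tag kept per position and an effective genome of 2.70e+9 bp, per the file headers. Broad RNAPII peaks came from MACS 2.0.9 with the same p cutoff, up to 2 tags kept per position and an effective genome of 1.87e+9 bp. Both Miz1 lists came from MACS 2.0.9 with the smaller genome size, but the p cutoff was 1e-02 for the fibroblast list and 1e-05 for the B cell list. Tags were 51 bp long. Control tags had been brought to the number of ChIP tags for Myc and RNAPII, while the control held 1.59 times as many tags as the fibroblast Miz1 library and 1.35 times as many as the B cell library. A deeper library lets weaker sites pass a fixed p, so the length of a list depends on its depth and on its cutoff as well as on binding.

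The number of tags inside a peak is a raw count of the authors, not scaled to library size. In the MACS 1.4.2 lists the significance of a peak is a score of −10 times log10 p, per the file headers. In the MACS 2.0.9 lists it is −log10 p and −log10 q, per the file headers. Fold enrichment is the ratio of ChIP tags to the local background of the control, as deposited. The false discovery rate of the MACS 1.4.2 lists is a percent that the authors' caller estimated by swapping ChIP and control. The MACS 2.0.9 lists also give the pileup signal at the summit, as deposited. All of these values belong to the authors and to their own list. They were used here to describe, rank or filter peaks within a list, never to measure a change between lists.

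Peaks were compared by position, with an overlap of at least 1 bp counted as shared. The chance level came from 100 random circular shifts of one list within each chromosome. Shares carry a Wilson 95% interval, which covers counting error only. For each factor the 6 lists were merged into regions, and a region was present at a time when a peak of that list lay in it. The annotation was GENCODE vM1 on NCBIM37, whose chromosome names and lengths were checked against the lists. For shares of peaks and regions, promoters were the 1000 bp either side of the transcription start site (TSS) of every annotated transcript, protein-coding or not. For counts of genes, they were windows of the same width around the TSSs of protein-coding transcripts of 22219 protein-coding gene symbols. 1 RNAPII peak at 2 h and 1 at 4 h ended past the end of its chromosome. CACGTG, the canonical E-box that Myc recognizes, was counted in the 200 bp around each summit and in windows of equal width 1000 bp away on both sides. After the data had been seen, the palindrome ATCGAT was counted in the same windows and GA repeats in the 100 bp around the summit.

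A gene list was compared with 10000 random lists of the same size, matched on whether members had an RNAPII promoter peak at 0 min, and its percentile describes these libraries only. The 18 lists held 393 symbols, of which Oaz2 was the only 1 not matched. They cover ribosome biogenesis, ribosomal proteins, nucleotide synthesis, polyamines, translation factors and tRNA synthetases, glycolysis, mitochondria, the cell cycle, CDK inhibitors, immediate-early genes, circadian genes, the Myc/Max/Mlx network, vesicle traffic and autophagy, and markers of fibroblasts, B cells, T cells or myeloid cells, neurons and hepatocytes. The lists, the comparisons, the alternatives marked as planned and the rule for named genes were fixed before the data were examined. Genes were ranked by the fold enrichment of their promoter peak within a list. The rule took the 12 highest genes with Myc at all 5 later times and not at 0 min, and the 10 highest with Myc at all 6 times. For RNAPII it took the 10 highest genes present at 2 h and 4 h but not at 0 min, and the 10 highest present up to 30 min but not at 2 h or 4 h. For Miz1 it took the 8 highest genes bound in fibroblasts only, in B cells only and in both. It added 11 genes that are always shown (Ncl, Npm1, Cad, Odc1, Cdk4, Nop56, Ldha, Ccnd2, Cdkn1a, Vamp4 and Ambra1), and examples of each gene list.

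RNAPII coverage of gene bodies was added after the lists had been explored. It is the percent of a gene, without its first 1000 bp, that lies under RNAPII peaks. Genes of at least 3000 bp with a promoter peak at 0 min entered, which left 9724 genes, and lists with at least 5 such members were compared with 10000 random lists matched on coverage at 0 min and gene length, or on coverage and promoter fold at 0 min. Genes outside the lists are named where the narrow and broad lists differed in the same direction between 0 min and 4 h, ranked by the smaller of the differences. Members of the lists were picked as examples after their values were seen, whether or not both callings had the same direction.

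Alternatives were a stricter peak threshold, equal numbers of peaks, stricter overlaps, broad in place of narrow RNAPII lists, other promoter and E-box windows, CACGCG beside CACGTG, unmatched random lists and leaving out a time. Those chosen after seeing the data were a common Miz1 threshold, leaving out GA repeats, counting on the 4 h list, assigning peaks by summit, joining narrow and broad lists, and other times for gene bodies. Tested on simulated data, 11 of 200 lists of random genes drawn from 20000 genes reached the 95th percentile, 3 of 3 planted overlap shares of 4000 peaks were recovered, and a gain of 30 points planted in 30 of 15870 gene bodies came out as 30.04. Miz1 peaks on contigs outside the main chromosomes stayed in the lists, but were assigned to no promoter and searched for no sequence. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9, with samtools 1.23.1 for the genome.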

Results

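Chromatin immunoprecipitation with sequencing (ChIP-seq) mapped where Myc and RNA polymerase II (RNAPII) sat on the genome while Myc was switched on. The cells were 3T9-MycER, a mouse embryonic fibroblast line with floxed c-myc alleles that carries MycER, a fusion of the transcription factor Myc to a hormone-binding domain. The fusion is held inactive until 4-hydroxytamoxifen (OHT), given here at 400 nM, binds it. Myc (antibody N262) and RNAPII (antibody N20) were profiled at 0, 10, 20 and 30 min and at 2 h and 4 h. Miz1, the zinc finger protein encoded by Zbtb17 and a DNA-binding partner of Myc, was profiled with antibody 10E2 in the same fibroblasts without OHT and in B cells from the spleen of wild-type mice. Peaks are not assigned here to endogenous Myc or to MycER.

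Each group held 1 library, so there are no replicates, no difference has a replicate check and no p-value between conditions is given. The Myc libraries held 28132063 to 33431447 tags and gave 19995 peaks at 0 min and 23617 at 4 h. The RNAPII libraries held 15276996 tags at 0 min, 16274905 at 30 min and 16268203 at 4 h, but 36396286 at 20 min. They gave 18877 narrow peaks at 0 min, 22602 at 20 min and 18222 at 4 h. The Miz1 libraries held 10164509 tags with 8310 peaks in fibroblasts and 24237295 tags with 4488 peaks in B cells. Median peak lengths were 1722 bp for Myc at 0 min, 2616 bp for RNAPII at 0 min and 302 bp for Miz1 in fibroblasts, so an overlap with a Myc or RNAPII peak places a site less exactly than an overlap of Miz1 peaks does.

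The first comparison asked which genes Myc bound before and after OHT. Many genes already carried Myc before OHT, among them 34 of 34 ribosome biogenesis genes (percentile 98.8 at 0 min, the highest possible for a list of that size). At 0 min 9921 of 22219 protein-coding genes had a Myc promoter peak, and 9615 had one at all 6 times. Among the 10 highest of these at 0 min were Ncl, which encodes the nucleolar protein nucleolin (87.0-fold), Riok2, a kinase of small ribosomal subunit maturation (86.2-fold), and Cdk7, a kinase of the general transcription machinery (81.0-fold). Genes that gained a called Myc peak were fewer, with 359 that had one at all 5 later times and none at 0 min. They included P2ry2, a receptor for extracellular nucleotides, Kremen1, a receptor of Wnt antagonists, and Nrtn, which encodes the growth factor neurturin.

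At Ncl the Myc peak of the 0 min list spanned chromosome 1, 88254199 to 88257368 (mm9), with its summit in an intron of Ncl. Its E-box lay at 88255360 to 88255365 in the sequence GGTCGCGCGACACGTGCGGGGCTCCG, and the 4 h peak held the same site. The Riok2 peak covered chromosome 17, 17510266 to 17512565, with its summit in the 5′ untranslated region and an E-box in GCTTCTTGAGCACGTGTTCTTACCTA. Ears2, the mitochondrial glutamyl-tRNA synthetase, and Ubfd1 shared a peak of 83.7-fold on chromosome 7. Pemt, an enzyme of phosphatidylcholine synthesis (79.9-fold), Pcbp1, an RNA-binding protein (79.7-fold), Ppp1r15b, a phosphatase subunit of the stress response (78.6-fold), Aldh18a1, an enzyme of proline synthesis (77.9-fold), and Fam119b (76.2-fold) completed the 10 highest. All 10 had their 0 min summit within 1000 bp of their own TSS, and 8 of the 10 had CACGTG in the 200 bp around it. Fold enrichments are the authors' own values for each list, so they rank genes within a time and do not measure a change between times.

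Of the 12 highest genes with Myc only after OHT, 7 had the 4 h summit within 1000 bp of their TSS and 5 of the 12 had CACGTG in the 200 bp around it. The P2ry2 peak (chromosome 7, 108159984 to 108161256, 31.5-fold at 4 h) lay between annotated transcripts at the TSS, over the E-box sequence CGCAGGGTCCCACGTGCCTGGAAGCG. The Lingo1 peak on chromosome 9 (24.6-fold), at a gene for a transmembrane protein of neurons, lay in an intron of Lingo1, 482 bp from a TSS, over CCGACACACGCACGTGGACAGACAGC. Kremen1 (26.0-fold), Nrtn (19.3-fold), Mtss1l (18.8-fold), Hsd3b7, an enzyme of bile acid synthesis (18.6-fold), and Heca (17.3-fold) had their summits at their own promoters without CACGTG. The Lpxn peak (43.1-fold) had its summit 3748 bp away from the Lpxn TSS, in an intron of Zfp91, and those of Prss8, Tmem102 and Anxa8 also lay more than 1000 bp from the TSS. An RNAPII promoter peak was present at 0 min at 249 of the 359 genes (69.4%, Wilson 95% interval 64.4 to 73.9), and at 96.1% (95.7 to 96.5) of the genes with Myc at all 6 times.

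Across the genome, 95.1% (94.8 to 95.4) of the Myc 0 min peaks overlapped a 4 h peak, and 79.8% (79.3 to 80.3) of the 4 h peaks overlapped a 0 min peak, against 3.16% for randomly shifted peaks. These intervals, like all others here, cover counting error only. The shares of the 10 min, 20 min, 30 min and 2 h peaks that overlapped a 0 min peak were 79.5%, 75.3%, 82.0% and 71.1%. Merged over the 6 lists, Myc peaks formed 29372 regions, of which 17674 (60.2%) were present at all 6 times, 2074 at all 5 later times but not at 0 min, and 82 at 0 min only. The 2074 regions were at promoters less often than those present at all times (22.2%, 20.5 to 24.1, against 53.6%, 52.9 to 54.4), and overlapped RNAPII 0 min peaks less often (20.2%, 18.5 to 21.9, against 62.9%, 62.2 to 63.6). With equal numbers of peaks from each list only 674 such regions were counted, and with the peaks above the median fold of each list 1315.

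Strong Myc sites were promoter sites that were there from the start, as the plot of Myc 4 h peaks by strength shows. Of the strongest 10% of the 4 h peaks by p, 99.6% (99.2 to 99.8) overlapped a 0 min peak, 83.9% lay at promoters and 37.0% held CACGTG. Of the weakest 10% these shares were 27.8% (26.0 to 29.6), 18.2% and 7.66%. All 4 h peaks together lay at promoters in 45.1% (44.5 to 45.7, against 7.67% for shifted peaks) and held CACGTG in 14.2% (13.7 to 14.6), against 2.61% in flanks of equal width. At 0 min the shares were 50.2% (49.5 to 50.9) and 15.8% (15.3 to 16.3). With CACGCG counted beside CACGTG the 4 h share was 23.8%, against 4.01% in the flanks.

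**Figure D1:**
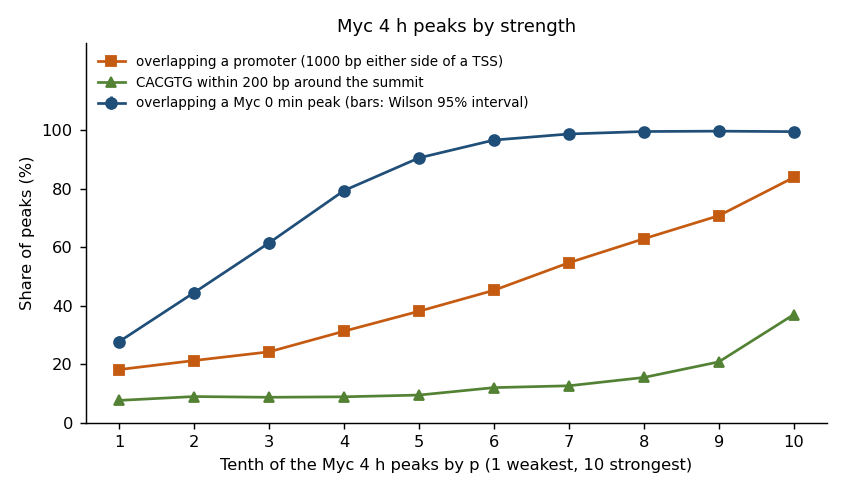
Share of Myc 4 h peaks (y axis, %) in each of 10 equal groups of the list ranked by p (x axis, 1 weakest to 10 strongest) that overlapped a Myc 0 min peak (circles, with Wilson 95% intervals), overlapped a promoter (squares) or held CACGTG in the 200 bp around the summit (triangles). The shares ranged from 27.8% to 99.7% for 0 min peaks, from 18.2% to 83.9% for promoters and from 7.66% to 37.0% for CACGTG.

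Several gene lists had Myc at every member. At 4 h Myc was at the promoters of 34 of 34 ribosome biogenesis genes, such as Ncl (120.0-fold), the fibrillarin gene Fbl (91.6-fold) and Gar1 (90.8-fold), and of 38 of 38 ribosomal protein genes. It was also at all members of the lists for nucleotide synthesis (25, such as Mthfd2 at 89.4-fold), translation factors and tRNA synthetases (25, such as Eif5a at 91.3-fold), mitochondria (24, such as the chaperone genes Hspd1 and Hspe1 under 1 peak of 82.5-fold), polyamines (7, such as the spermidine synthase gene Srm at 92.9-fold), the cell cycle (25, such as Ccnd1 at 74.9-fold) and immediate-early genes (23, such as Fosl1 at 49.4-fold). Glycolysis genes had a peak in 17 of 18 members, with pyruvate kinase Pkm2 at 74.7-fold and lactate dehydrogenase Ldha at 73.0-fold, and without one the lactate transporter gene Slc16a3. Vesicle and autophagy genes had peaks in 28 of 30, fibroblast markers in 20 of 24, circadian genes in 12 of 16, the Myc/Max/Mlx network in 11 of 14 and CDK inhibitors in 5 of 7. Markers of cell types that the culture should not hold were bound in 2 of 22 (B cells), 1 of 20 (T and myeloid cells), 2 of 20 (neurons) and 2 of 20 (hepatocytes).

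Among random lists matched on RNAPII promoter peaks at 0 min, 3 of the 18 lists lay at or above the 95th percentile at 4 h: ribosome biogenesis (97.0), ribosomal proteins (97.8) and fibroblast markers (96.7). A fully bound list cannot pass a limit set by its size, which was 93.5 for 25 members, 92.9 for 24, 92.4 for 23 and 72.1 for 7, so the other fully bound lists could not reach the 95th percentile. The values for ribosome biogenesis and ribosomal proteins are likewise the limits for 34 and 38 members. They do not set these lists apart from the shorter lists that were also fully bound. The matched random lists had a median of 31 of 34 bound members for ribosome biogenesis, 35 of 38 for ribosomal proteins and 23 of 25 for nucleotide synthesis. Without that matching 13 lists did, and with the peaks above the median fold 7 did. Among the 359 genes with Myc only after OHT, vesicle and autophagy genes had 3 of 30 members (Exoc4, Stx8 and Vps39, percentile 98.0), and fibroblast markers had 1 of 24, the collagen gene Col6a1.

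The second comparison asked where RNAPII sat through the time course. The number of genes with a called RNAPII promoter peak was similar before and after OHT, with 10536 at 0 min and 10385 at 4 h. At all 6 times 9663 had one. Such calls do not measure how much RNAPII a promoter held. The stretch of RNAPII peaks along gene bodies differed between gene groups. Over ribosome biogenesis genes, mean coverage of the gene body by RNAPII peaks was 49.4% at 0 min, 77.9% at 10 min, 78.5% at 30 min and 77.0% at 4 h (33 genes). Nucleotide synthesis genes had 37.8% at 0 min, 53.4% at 30 min and 53.6% at 4 h (25 genes). Fibroblast markers, which encode collagens and other matrix or cytoskeletal proteins, had 64.7% at 0 min and 62.2% at 4 h in the narrow lists, and 47.1% and 31.3% in the broad lists (17 genes).

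The gene-body measure was chosen after the lists had been explored, and its group means have no replicate error. For ribosome biogenesis, coverage was higher at 30 min than at 0 min in 23 of 33 genes and lower in none of them in the narrow lists, and higher in 25 and lower in 2 in the broad lists, where the mean was 19.9% at 0 min and 40.1% at 30 min. Rrp9 encodes a protein of a small nucleolar RNA complex that processes ribosomal RNA. The body of the gene was covered over 2.21% at 0 min and 100% from 10 min on. Its RNAPII peak spanned chromosome 9, 106377439 to 106380757 at 0 min and 106377540 to 106388937 at 30 min. Coverage at 0 min and 30 min was 2.3% and 94.9% for Pes1, 0.33% and 85.2% for Polr1b, a subunit of RNA polymerase I, and 16.3% and 100% for Nop16, whereas Ncl, Npm1 and Nop56 were fully covered at both times. In the broad lists coverage at 30 min was 49.8% for Rrp9 but only 2.77% for Pes1, 2.43% for Polr1b and 14.9% for Nop16, so the extent at single genes depends on the calling. The list's mean difference of 29.1 points from 0 to 30 min lay at the 100th percentile of random lists matched on coverage at 0 min and length.

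**Figure D2:**
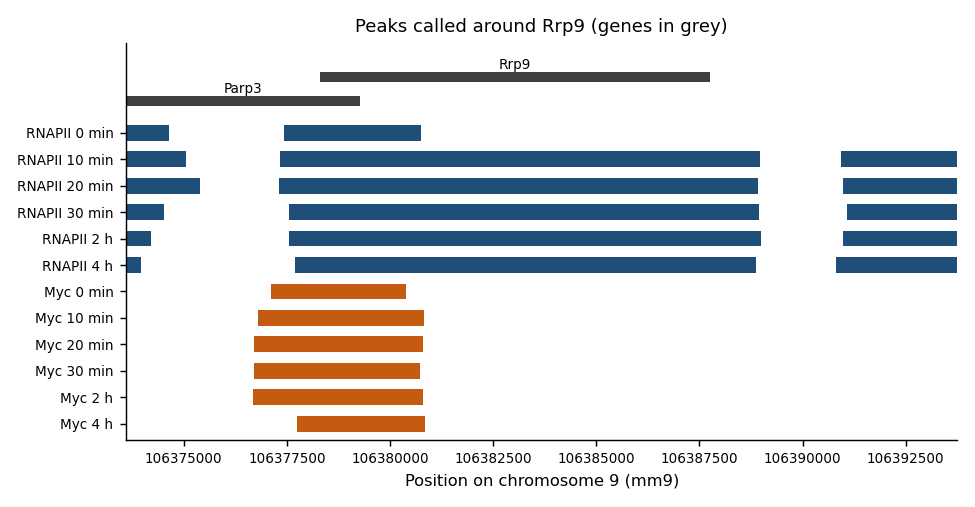
Peaks called around Rrp9 (x axis, position on chromosome 9 in mm9; y axis, the library) in the narrow RNAPII lists (blue) and the Myc lists (orange), with genes in grey. The RNAPII peak over Rrp9 ended at 106380757 at 0 min and at 106388962 at 10 min, while the Myc peaks stayed at the start of the gene.

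Other gene lists also had higher mean coverage at 30 min than at 0 min. These included circadian genes (percentile 96.1, and 99.7 in the broad lists), the Myc/Max/Mlx network (97.3, but 43.6 in the broad lists) and immediate-early genes (94.6 and 92.0). Mitochondrial genes had 49.8% at 0 min, 62.9% at 30 min and 61.6% at 4 h (percentile 99.8 at 30 min), and glycolysis genes 49.1%, 64.2% and 54.0% (99.9 at 30 min, but 86.2 in the broad lists). Translation factors and tRNA synthetases had 78.7%, 88.2% and 84.6% (99.9 at 30 min). Nucleotide synthesis reached the percentile 99.9 at 30 min, with Cad, the enzyme that starts pyrimidine synthesis, covered over 4.19% at 0 min, 63.9% at 30 min and 85.9% at 4 h, and the purine enzyme gene Ppat over 5.53%, 77.3% and 75.8%. In the broad lists Cad was covered over 0.37% at 30 min and Ppat over 17.8%. Cell cycle genes had 51.9%, 54.3% and 57.7%, at the percentiles 63.0 (30 min) and 97.0 (4 h), but 91.5 at 4 h in the broad lists. Ccne2, a cyclin of S phase entry, had 14.8%, 100% and 100%, but 9.45%, 6.18% and 30.9% in the broad lists. Ribosomal protein genes were already covered over 95.4% at 0 min. Across all 9724 genes the mean was 21.3% at 0 min, 24.3% at 30 min and 22.5% at 4 h. It was 25.4% at 2 h, 27.7% at 10 min and 32.8% at 20 min. Over the 6 times this mean followed the tag numbers of the libraries, from 0 min, the shallowest, to 20 min, the deepest. Depth is thus not set apart from time in the mean of all genes.

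**Figure D3:**
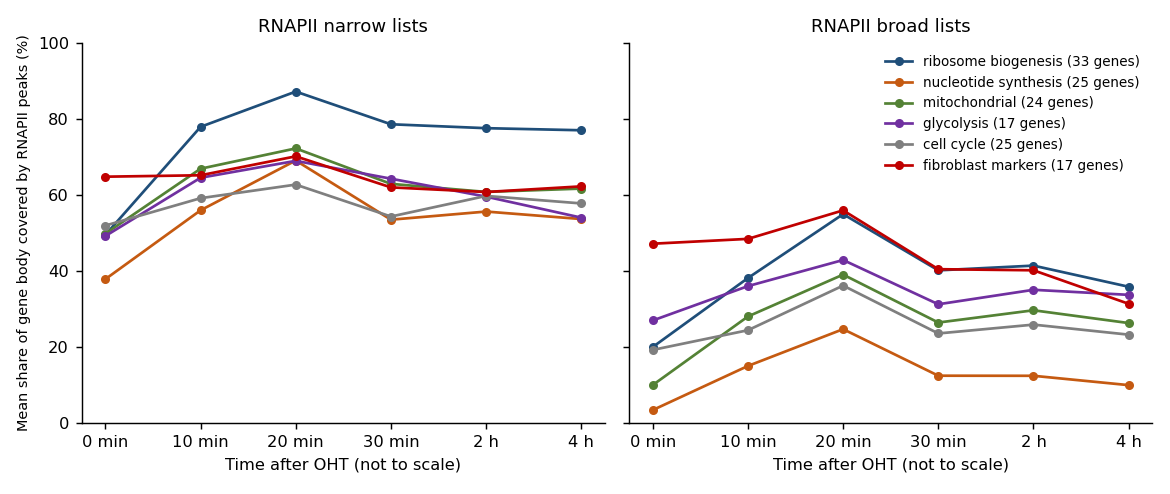
Mean share of the gene body covered by RNAPII peaks (y axis, %) at each time after OHT (x axis, not to scale) for 6 gene lists, in the narrow lists (left) and the broad lists (right). Ribosome biogenesis genes had 49.4% at 0 min and 78.5% at 30 min in the narrow lists, and 19.9% and 40.1% in the broad lists; the 20 min library held 36396286 tags, more than any other.

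Gene-body coverage also differed with the strength of Myc at the promoter. In the 20% with the highest fold among genes with a Myc 4 h promoter peak, mean RNAPII coverage was 33.9% at 0 min, 44.8% at 30 min and 42.1% at 4 h (1813 genes). In the 20% with the lowest it was 11.9%, 10.9% and 9.94% (1814 genes), and in the 658 genes without a Myc 4 h promoter peak 17.4%, 16.3% and 16.7%. Coverage was higher by over 20 points at 30 min in 411 genes of the highest group and lower by as much in 58. In the lowest group these counts were 39 and 68. At 20 min, in the deepest library, the means were 55.2% in the highest group, 17.5% in the lowest and 20.8% without Myc. Genes entered only with an RNAPII promoter peak at 0 min, so those near the calling threshold then could tend to be lower later. The differences between these groups are thus not set apart from depth, calling or this entry rule.

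At promoters, a small set of genes had an RNAPII peak at 2 h and 4 h and none at 0 min in the narrow lists, and 45 genes had one up to 30 min and none at 2 h or 4 h. The former set held 83 genes with a Myc promoter peak at 4 h, which were 65.9% (57.2 to 73.6) of it. That share was low for genes with RNAPII. Of the 9724 genes with an RNAPII promoter peak at 0 min in the gene-body comparison, only 658 had no Myc 4 h promoter peak. The former set was led at 4 h by Astl (55.01-fold), Col5a1, a fibrillar collagen (49.7-fold), Coro1a, an actin-binding protein (48.9-fold), Gm88 (46.5-fold), Zfp639 (44.8-fold), Zfr (35.7-fold), Chd5 (35.4-fold), Nt5dc2 (32.1-fold), Gm10774 (31.4-fold) and Tjap1 (27.4-fold). In 7 of these 10 the summit lay more than 1000 bp from the TSS, at Astl in the 5′ untranslated region of the phosphatase gene Dusp2, at Coro1a in that of Bola2 and at Chd5 in an intron of Rpl22. The rule sets no condition on 10 to 30 min, so these are not late peaks only. Astl, Coro1a, Gm88, Chd5, Nt5dc2, Gm10774 and Tjap1 already had a narrow peak at 10 min. Zfr had one at 30 min, while Col5a1 and Zfp639 had no narrow peak before 2 h. The set depended on the calling: only 34 of its genes were also in the same class in the broad lists, and Col5a1 had a 0 min peak of 67.9-fold there, Zfr of 36.5-fold, Tjap1 of 29.9-fold and Gm88 of 22.8-fold.

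Among the 45 genes without RNAPII at the late times, the 10 highest at 0 min were Tinagl1, a matrix protein gene (26.8-fold), Lmcd1, a cofactor with LIM domains (25.5-fold), Gm17305 (25.2-fold), the peroxisomal membrane protein gene Pxmp4 (17.3-fold), Mospd1 (16.2-fold), Zfp947 (16.1-fold), Pi4k2b, a phosphatidylinositol kinase gene (14.9-fold), 5031439G07Rik (12.2-fold), the kinase gene Map3k9 (12.2-fold) and Ninj2 (12.01-fold). The Tinagl1 peak lay on chromosome 4, 129848798 to 129853043, with its summit in the 5′ untranslated region. 5 of the 45 were in the same class in the broad lists, and there Lmcd1 had a peak at 2 h (11.2-fold) and at 4 h (8.82-fold), and Pxmp4 at 2 h (7.8-fold). A Myc promoter peak at 4 h was present at 31 of the 45 (68.9%, 54.3 to 80.5). This share too was lower than in the gene-body comparison, where 658 of 9724 genes had no Myc 4 h promoter peak.

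Of the RNAPII 4 h peaks, 82.6% (82.1 to 83.2) overlapped a 0 min peak, against 5.66% for shifted peaks, and 58.8% (58.0 to 59.5) lay at promoters, against 10.9%. With summits at most 100 bp apart the overlap was 45.6%. Of the weakest 10% of the 4 h peaks 47.0% (44.7 to 49.3) overlapped a 0 min peak, and of the strongest 99.9% (99.6 to 100.0). Merged over the 6 times there were 23745 regions, of which 10912 (46.0%) were present throughout, 350 at all 5 later times but not at 0 min, and 520 at 0 min only. The regions present throughout lay at promoters in 81.0% (80.3 to 81.8).

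The third comparison set Myc against RNAPII at the same time. Myc and RNAPII peaks overlapped at the promoters of genes such as Ncl, where at 0 min the Myc peak lay inside an RNAPII peak of chromosome 1, 88238590 to 88258831, that ran over the gene. Ldha, lactate dehydrogenase, had an RNAPII peak of 113.5-fold and a Myc peak of 44.0-fold at 0 min, and Cdk4, a cyclin-dependent kinase, 40.4-fold and 30.5-fold. The share of Myc peaks that overlapped an RNAPII peak was 59.5% (58.8 to 60.1) at 0 min, 53.1% at 10 min, 54.5% at 20 min, 53.7% at 30 min, 45.1% at 2 h and 49.1% (48.5 to 49.8) at 4 h, against 4.40% for shifted peaks at 4 h. Conversely 58.2% (57.5 to 58.9) of the RNAPII 0 min peaks and 59.1% (58.4 to 59.8) of the 4 h peaks overlapped a Myc peak of the same time. The Myc lists held 19995 peaks at 0 min, 27388 at 2 h and 23617 at 4 h. With the 18222 strongest peaks of each 4 h list, 58.7% of the Myc peaks overlapped an RNAPII peak. The lower shares after 0 min are thus not set apart from the length of the Myc lists. With summits at most 100 bp apart, 18.8% of the Myc 4 h peaks met an RNAPII peak. CACGTG was in 5.17% (4.86 to 5.50) of the RNAPII 4 h peaks, against 2.79% in their flanks.

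Of the genes that are always shown, Odc1, the enzyme that starts polyamine synthesis, had Myc peaks of 22.4-fold in the 0 min list and 49.1-fold in the 4 h list, and Npm1, which encodes nucleophosmin, 60.5-fold and 79.1-fold over intronic E-boxes. Ccnd2, a D-type cyclin gene, had 15.2-fold and 32.8-fold, and Nop56, a box C/D small nucleolar RNA protein gene, 33.6-fold and 53.8-fold. Cdkn1a, the CDK inhibitor p21, had a Myc peak of 11.3-fold in the 0 min list and 18.3-fold in the 4 h list, with the summit 1561 bp downstream of the TSS in an intron at 4 h and an RNAPII summit at the TSS.

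The fourth comparison asked where Miz1 was bound in fibroblasts and in B cells, and whether its sites held Myc. Miz1 marked a shared set of promoters in both cell types that was led by Tmbim4 (293.5-fold in the fibroblast list, 141.8-fold in the B cell list), the ribosomal protein gene Rpl22 (273.5 and 94.0), Vps28, a component of endosomal sorting (272.6 and 66.7), the proteasome subunit gene Psmd3 (268.9 and 89.1) and the divergent pair Dctn5 and Palb2 under 1 peak (245.8 and 83.1). Znhit3 (242.1 and 86.4) and the spliceosome gene Snrpb2 (236.1 and 95.7) followed. In all, 540 genes had a Miz1 promoter peak in both lists, where 100.3 would be expected of independent lists over all genes, 1292 in fibroblasts only and 677 in B cells only. Among genes with RNAPII at 0 min 528 had both, where 174.7 would be expected. Among promoters with a peak in a single list, the highest fold was 48.4 in fibroblasts (Ncam1, a neural cell adhesion molecule) and 67.8 in B cells (Gpr19, an orphan receptor gene).

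The Tmbim4 peak spanned chromosome 10, 119645420 to 119646272 in fibroblasts and 119645411 to 119646385 in B cells, and that of Vps28 chromosome 15, 76455867 to 76457032, over the 3′ untranslated region of the neighbouring Tonsl. Fibroblast-only promoters, after Ncam1 (chromosome 9, 49606767 to 49607416), were led by Lrba and Mab21l2 under 1 peak (48.0-fold), by the type IV collagen pair Col4a5 and Col4a6 (35.8-fold), by Gart, a purine synthesis enzyme, with Son (35.0-fold, over the E-box sequence CCGTGCAAAGCACGTGGGCTTTTCGC) and by Psmb3 (31.4-fold). B cell-only promoters, after Gpr19 (chromosome 6, 134846212 to 134846951, in its intron), were led by Dcaf5 (64.8-fold), the protease gene Ctse (62.8-fold), Aff1 (59.5-fold), Zfyve1 (40.2-fold), Rgs18, a regulator of G-protein signalling (39.9-fold), Ppid (39.3-fold) and D030056L22Rik (34.9-fold). Vamp4 and Ambra1, genes of vesicle fusion and of autophagy, had Miz1 peaks in both lists (131.1 and 168.3-fold in fibroblasts, 104.7 and 86.4-fold in B cells).

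Genome-wide, 10.7% (10.1 to 11.4) of the fibroblast peaks overlapped a B cell peak, against 0.131% for shifted peaks, and 19.9% (18.7 to 21.1) of the B cell peaks overlapped a fibroblast peak. Sharing was concentrated among strong peaks, with 45.7% (42.4 to 49.1) of the strongest 10% of the fibroblast peaks and 1.44% (0.828 to 2.51) of the weakest. The p cutoff of the fibroblast list was looser, and 4039 of its 8310 peaks had a p above 1e-05. At a p of at most 1e-05 in both lists 17.9% of the fibroblast peaks overlapped a B cell peak, and at a −log10 q of at least 10, 38.9%.

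**Figure D4:**
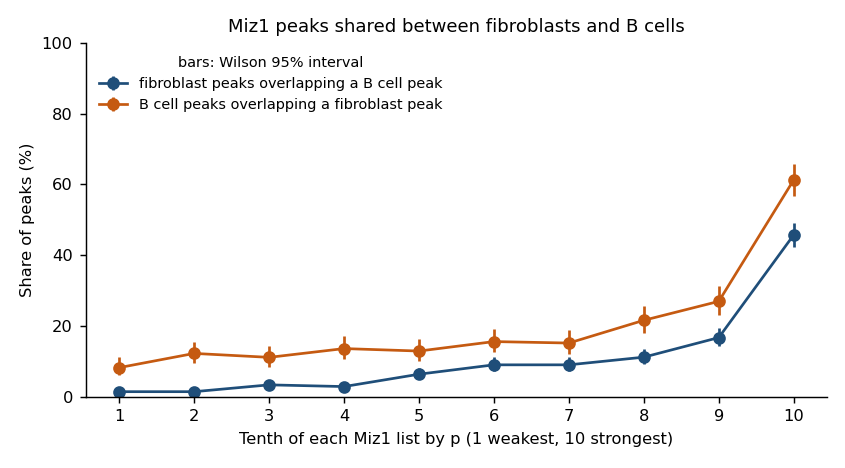
Share of Miz1 peaks (y axis, %, with Wilson 95% intervals) in each of 10 equal groups of a list ranked by p (x axis, 1 weakest to 10 strongest) that overlapped a peak of the other cell type, for fibroblast peaks (blue) and B cell peaks (orange). The shares were 1.44% and 8.24% in the weakest group and 45.7% and 61.2% in the strongest.

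By gene group, fibroblast Miz1 was at the promoters of 9 of 25 cell cycle genes (percentile 99.2), such as the replication gene Mcm7 (25.7-fold) and the cyclin gene Ccne1 (7.45-fold), and of 3 of 7 CDK inhibitors (98.2), which were Cdkn2a (10.9-fold), Cdkn2b (6.43-fold) and Cdkn1a (4.47-fold). It was at 2 of 34 ribosome biogenesis genes (4.58). These fibroblast counts include weak peaks, since 4039 of the 8310 peaks of that list had a p above 1e-05. The median fold of the list was 5.96, so the Cdkn1a peak lay below it. Gene lists were not counted again at a stricter Miz1 threshold. In B cells, Miz1 was at 4 of 22 B cell markers, which were the surface receptor genes Cd22 (31.1-fold) and Cd79a (8.77-fold) and the transcription regulator genes Spib (7.79-fold) and Pou2af1 (3.51-fold), while fibroblast Miz1 was at none of the 22. Vesicle and autophagy genes had 7 of 30 members bound in B cells and 8 of 30 in fibroblasts (93.2), and the neuron markers Syp and Dlg4 were 2 of 20 bound in B cells. No percentile is given for B cells, since the random lists were matched on RNAPII in fibroblasts. No CDK inhibitor had a Miz1 promoter peak in B cells, and 1 of 25 cell cycle genes had one. The p cutoff of the B cell list was stricter than that of the fibroblast list. Lower counts in B cells therefore do not set cell type apart from calling.

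Most genes with Miz1 also had Myc before OHT. Of the genes with Miz1 in both cell types 513 of 540 (Wilson interval 92.8 to 96.5%) had a Myc 0 min promoter peak, of those with Miz1 in fibroblasts only 89.6% (87.8 to 91.1), of those with it in B cells only 77.8% (74.6 to 80.8) and of those without it 39.2% (38.5 to 39.9). RNAPII at 0 min followed the same order, with 97.8%, 90.2%, 82.6% and 42.0%. By peaks, 42.1% (41.0 to 43.1) of the fibroblast Miz1 sites overlapped a Myc 0 min peak, against 1.94% for shifted peaks, and 45.8% (44.7 to 46.8) a Myc 4 h peak. The share was 58.5% at a −log10 q of at least 10, 26.3% with as many Myc as Miz1 peaks, 11.6% with summits at most 100 bp apart and 0.481% when the overlap had to cover at least 0.5 of both peaks, a condition that Myc peaks of 1722 bp and Miz1 peaks of 302 bp rarely meet.

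CACGTG was rare at Miz1 sites: 3.00% (2.65 to 3.39) of the fibroblast peaks and 3.10% (2.63 to 3.65) of the B cell peaks held CACGTG, against 2.44% and 2.90% in their flanks. Among Miz1 peaks at promoters the shares were 5.16% in fibroblasts and 4.77% in B cells. The palindrome ATCGAT and GA repeats were looked at after the data had been seen. ATCGAT was in 4.71% (3.51 to 6.31) of the fibroblast peaks shared with B cells and in 0.660% (0.500 to 0.872) of the others. GA repeats (GAGAGAGA or its complement) were in 10.5% (9.83 to 11.1) of the fibroblast peaks and 20.9% (19.7 to 22.1) of the B cell peaks, against 2.26% and 2.18% in their flanks, and in 0.974% of the Myc 4 h peaks.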

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

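Neither count here was tested against an explanation, and both were looked at only after the lists had been seen. The Miz1 lists hold a few peaks on contigs outside chromosomes 1 to 19, X and Y, where no genes or sequence motifs were searched. There were 12 such peaks in the fibroblast list, all on unplaced contigs, with a fold of up to 17.9. The B cell list held 10, of which 2 lay on the mitochondrial genome and 8 on unplaced contigs, with a fold of up to 11.8. They drew attention because they are signal in sequence that the promoter comparisons leave out, and their numbers lie above the limit of 3 that a count of 0 allows. No explanation, technical or biological, was tested for them.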

How the results depend on the processing

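The settings with a common Miz1 threshold, without GA repeats, counting on the 4 h list, by summit, or with narrow and broad lists joined were chosen after seeing the data, as was everything on gene bodies. Of 52 planned comparisons of a value with an alternative 11 stayed and 41 moved. Of 16 added later 12 stayed and 4 moved. A share stayed if it lay within the counting interval, a count if within 1.5 times, and a gene-body gain if within a narrower limit. The mean gain over ribosome biogenesis bodies stayed positive in every alternative, while shares and counts have no direction that could turn. No paired analysis was possible because each group held 1 library. The cause was not tested except where the setting itself makes a list shorter or an overlap stricter.

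With the peaks above the median fold of each list, the share of Myc 4 h peaks overlapping a 0 min peak was 76.1%, Myc regions gained after 0 min were 1315, RNAPII 4 h peaks overlapping a 0 min peak 92.4%, Myc 4 h peaks overlapping RNAPII 58.2%, Miz1 fibroblast peaks overlapping B cell peaks 12.8%, those overlapping Myc 35.1%, Myc peaks at promoters 60.3%, Myc peaks with CACGTG 20.4% and high gene lists 7. At a −log10 q (or p) of at least 10 the RNAPII share was 84.0%, Myc with RNAPII 50.7%, Miz1 in B cells 38.9%, Miz1 with Myc 58.5%, promoters 47.6% and CACGTG 14.8%. With the same number of peaks from each list the Myc share was 88.6%, gained Myc regions 674, RNAPII 81.7%, Myc with RNAPII 58.7%, Miz1 in B cells 17.3%, Miz1 with Myc 26.3%, promoters 49.8% and CACGTG 15.3%.

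With stricter overlap of both peaks the Myc share was 78.1%, RNAPII 68.6%, Myc with RNAPII 35.0%, Miz1 in B cells 8.80% and Miz1 with Myc 0.481%. With summits at most 100 bp apart these were 60.3%, 45.6%, 18.8%, 9.29% and 11.6%. With broad RNAPII lists the RNAPII share was 78.1% and Myc with RNAPII 42.8%. Promoters of 500 bp and 2000 bp either side gave 43.7% and 47.9%, and E-box windows of 100 bp and 400 bp gave 10.5% and 17.6%, while CACGCG counted beside CACGTG gave 23.8%. Random lists not matched gave 13 high gene lists. At p of at most 1e-05 in both lists 17.9% of the fibroblast Miz1 peaks overlapped a B cell peak, and without GA repeats 9.45%.

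Leaving out 1 later time gave 2126 to 2634 gained Myc regions. Counts of RNAPII promoters stayed within 1.5 times in the broad lists. There 160 were present at 2 h and 4 h and absent at 0 min, and 38 were present up to 30 min and absent later. The genes were largely different, with 34 and 5 shared. The mean gain over ribosome biogenesis bodies was 20.2 points in the broad lists and 37.7 at 20 min, in the deepest library. Depth limits what a missing peak means, since a site under the calling threshold is not called. A promoter without a narrow RNAPII peak is not always weakly bound: 8 (0 min) to 69 (20 min) promoters per time had a broad peak of over 30-fold and no narrow peak.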

Other observations

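Gene-body coverage was explored after the data had been seen, and the tests of depth for Myc and RNAPII, of calling for RNAPII, of 0 min enrichment for Myc and of the common Miz1 threshold were chosen only after the result was seen. RNAPII covered more of the body of several genes at 4 h than at 0 min in both callings. The mitochondrial ribosome gene Mrps26 was covered over 36.5% at 0 min and 100% at 4 h, the apoptosis gene Bax over 35.4% and 100%, Ifrd2 over 36.4% and 100%, and the sialyltransferase gene St6galnac4 over 5.86% and 100%. Other genes were covered less at 4 h: the urokinase gene Plau was covered over 100% at 0 min and 7.35% at 4 h, the adhesion cofactor gene Tgfb1i1 over 100% and 17.9%, and the matrix metalloprotease gene Mmp14 over 100% and 60.6%. In the broad lists Plau had 59.6% and 0%, and Mmp14 45.8% and 13.4%. In both callings 48 genes were higher by over 20 points at 4 h and 16 lower, while in the narrow lists alone 716 were higher and 476 lower. The genes named were picked from those of both callings after their values were seen.

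Fibroblast markers had a mean of 47.1% at 0 min and 31.3% at 4 h in the broad lists, lower in 12 of 17 genes and higher in 2 (percentile 0.05), but 64.7% and 62.2% in the narrow lists (percentile 78.5). The smooth muscle genes Tagln and Acta2 had broad coverage of 72.6% and 68.7% at 0 min and 7.37% and 13.8% at 4 h, but narrow coverage of 100% for both at 0 min and of 100% and 87.4% at 4 h. CDK inhibitors had 72.2% at 0 min, 54.7% at 30 min and 59.9% at 4 h over 5 genes, and 24.02%, 12.1% and 16.7% in the broad lists. Immediate-early genes had 60.8%, 69.1% and 54.4%, with Btg2 at 32.8%, 100% and 11.4%, but at 0% at these times in the broad lists. Circadian genes had 26.1%, 37.1% and 25.7%, with Per1 at 47.2%, 97.1% and 48.4%, but at 21.2%, 35.2% and 5.36% in the broad lists. Polyamine genes had 59.5%, 70.0% and 64.5%, the Myc/Max/Mlx network 37.6%, 49.4% and 38.7%, and vesicle and autophagy genes 9.02%, 11.3% and 10.7%. In the broad lists immediate-early genes had 46.8%, 51.9% and 41.8%, circadian genes 11.3%, 21.8% and 14.0%, polyamine genes 13.9%, 29.1% and 21.1%, the network 18.6%, 19.5% and 16.8%, and vesicle and autophagy genes 1.09%, 2.01% and 0.45%. The hexokinase gene Hk2 had 3.25%, 95.1% and 8.44%, but 1.90%, 9.13% and 1.33% in the broad lists.

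RNAPII peaks covered more of ribosome biogenesis gene bodies at 30 min than at 0 min. Depth is argued against as the whole cause, since the 10 min library, with 19999678 tags against 16274905 at 30 min, gained 0.977 times as much, although the 20 min library, with 36396286 tags, gained 37.7 points against 29.1 at 30 min. For the 19 members with no other protein-coding gene within 1000 bp, the gain was 1.14 times that of all members. This argues against reach-through from protein-coding genes that close. It does not exclude reach-through from farther away, since the longest narrow peak at 30 min spanned 124267 bp. With matching on promoter fold the percentile was 100.0. Those lists were not matched on Myc strength, with which coverage in the deepest library differed. Stronger enrichment at strongly bound genes is therefore not settled. A difference in peak calling cannot be told apart by the percentile of 100.0 among lists matched on coverage and length, since coverage in the deepest library did not differ alike across genes. An effect of OHT without MycER and the handling of single libraries were not tested and stay open.

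Myc regions seen at all later times but not at 0 min had several technical candidates. Lower depth at 0 min is argued against, since that library held 1.08 times the median tags of the later ones. Regions missed only at 0 min were 5.44 times those missed only at the highest later time. This does not test random crossing of the calling threshold, since the 0 min list was the shortest and a shorter list misses more weak regions. With equal numbers of peaks from each list the regions fell from 2074 to 674. Weaker enrichment at 0 min needs these regions to be among the weakest, and their median rank in the 4 h list was at percentile 23.3. Weak sites filled only after activation could give the same rank, so it does not separate these explanations.

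Most fibroblast Miz1 peaks overlapped no B cell peak. At a p of at most 1e-05 in both lists 4271 fibroblast peaks remained, of which 17.9% overlapped a B cell peak. The looser cutoff does not account for the unshared peaks among these, though it may account for others. GA repeats lay in 9.66% of the unshared fibroblast peaks, and without peaks at GA repeats 9.45% overlapped. Only 891 of 8310 fibroblast peaks overlapped a B cell peak at all. Neither setting could therefore have made most peaks shared, so neither tests its explanation further. A difference between the cell types and the difference in depth between these single libraries were not tested and stay open.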
